A study of Mus musculus with 23 samples.

How the data were processed

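RNA was sequenced from mouse splenic CD4+ T cells that were sorted as CD45+CD3+CD4+CD8- cells and cultured for 72 h, per the labels' protocols. All cultures held IL-2 at 30 IU/ml. They received either nothing further (unstimulated) or antibodies against CD3 and CD28 (stimulated), each without niacin or with 5 mM niacin. Cells were labelled wild type or Gpr109a-/-, and Gpr109a is the earlier name of Hcar2, the receptor for niacin. RNA was amplified with the SMART-seq V4 kit and sequenced on an Illumina HiSeq instrument in paired-end mode, per the labels' protocols.

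The values used were the deposited counts of reads per gene. Reads were trimmed with Trimmomatic 0.38, aligned with STAR 2.7.0e to the mouse genome (GRCm38.p5 and mm10 are both named) and counted with featureCounts 1.6.3, per the submitters' processing notes. The strand setting of the counting and the release of the annotation are not given in the sources used here. The table held 53379 gene IDs in 23 libraries, and no count column was left without a sample. Symbols were found for 53274 IDs in GENCODE vM21, and 51335 IDs had the same chromosome, start and end there. Coordinates are those of the deposited table. No read was counted for 23012 genes, and 159 IDs shared a symbol with another ID.

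Libraries were grouped by stimulation, niacin and genotype label into 8 groups. Each held 3 libraries, apart from the unstimulated knockout-labelled cells with niacin, which held 2 (numbers 2 and 3; a library numbered 1 of this group was not analysed here). The labels do not say whether replicates were separate animals, so p-values measure the spread between these libraries only. Totals ran from 13205565 to 30090018 counts, with a median of 24007159. The lowest total was that of library 3 of the unstimulated knockout-labelled cells, and the next lowest was 20604050. The intervals and the limits set by a count of 0 (3 counts) cover counting error only.

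Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, a mean per group over all 23 libraries, TMM factors, filterByExpr with its minimum count of 10). This left 16882 genes. The p-values were adjusted by the Benjamini-Hochberg method within each comparison, at a threshold of 0.05. Standard errors of log2 fold changes were taken from the F statistic. The common biological coefficient of variation was 27.4%, and the fit had 15 residual degrees of freedom. Normalised levels are CPM with TMM factors, given as mean ± SD. The 4 genotype comparisons, the 4 niacin comparisons, the 2 stimulation comparisons and 3 tests of effects differing by genotype were chosen before the data were examined. So were 26 gene lists, the rule for naming genes and the other settings tried. A further 2 comparisons, the average effect of niacin over the 4 backgrounds and the average genotype difference over the 4 conditions, were added after the data had been examined.

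The lists covered T cell activation, naive and quiescent T cells, T cell cytokines, Th1, Th2, Th17 and regulatory T cells. They also covered the cell cycle, glycolysis, oxidative phosphorylation (nuclear genes), the mitochondrial genome, NAD metabolism, ATF4 and the integrated stress response, p53 targets, the type I interferon response, cholesterol synthesis, cAMP responsive genes, NRF2 targets, the hypoxia response, heat shock, and receptors and transporters of hydroxycarboxylic and short-chain fatty acids. Markers of B cells, CD8 T cells, NK and gamma delta T cells, myeloid and dendritic cells, and erythroid cells and platelets made up the others. Each list was described by its counts of passing genes, its median log2 fold change and camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and again with the estimated correlation. The camera p-values were adjusted by the Benjamini-Hochberg method over the lists within a comparison. The mean log2 CPM of each list per library was also compared by a two-sided exact permutation of the niacin or genotype label within the other conditions, chosen after the data had been examined.

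The other settings were DESeq2 1.42.0 (Wald test, its size factors, no independent filtering), RLE factors, no filter on low counts, the replicate number as a block, limma voom with sample quality weights, only the compared groups in the fit, and leaving out each library in turn. Settings chosen after seeing the data left out libraries 1 and 2 of the stimulated wild-type-labelled cells with niacin together, and left out library 3 of the unstimulated knockout-labelled cells from comparisons it was not part of. The gene lists were also counted without these libraries, and without library 1 of the unstimulated wild-type-labelled cells. The tables were read in R 4.3.3 with the package data.table, version 1.17.8.

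Named genes are Hcar2, Hcar1 and Ffar2 in each comparison. Per comparison they are also up to 6 genes per direction with the largest log2 fold changes among those past the threshold, at 5 CPM or more in the higher group and with no overlap between the libraries compared. Predicted models, pseudogenes, Rik clones and antigen receptor segments were left out of that choice. Up to 4 members of each list with the smallest passing p were added. Genes outside the rule are said to be so, and genes named in 1 comparison are also given in others.

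The scripts were tested on simulated data, with 100 genes changed 2-fold and 100 changed 4-fold. For the genotype comparison in stimulated cells (16487 genes) 44% and 87% were recovered with 2 false calls. For niacin in unstimulated knockout-labelled cells (16483 genes) 44% and 83% were recovered with 8 false calls. For niacin in stimulated wild-type-labelled cells (16476 genes) 51% and 89% were recovered with 8 false calls. Copies of Rplp0 were found by aligning its transcript to the annotated transcripts with blastn. Reads were not aligned again. Some results of single genes are not reported here.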

Results

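Transcript counts were compared between 8 groups of mouse splenic CD4+ T cells, labelled wild type or knockout for the niacin receptor gene Hcar2 (Gpr109a). Cells were kept in IL-2 alone or stimulated through CD3 and CD28, each without or with niacin. Of the 23 libraries, 12 were labelled wild type and 11 knockout, with 3 per group except for 2 of unstimulated knockout-labelled cells with niacin. Total counts ran from 13205565, in library 3 of the unstimulated knockout-labelled cells, to 30090018, with the next lowest at 20604050.

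A few libraries stood apart. Library 3 of the unstimulated knockout-labelled cells had 4.42% of its counts on rRNA-like genes and the lowest TMM factor, 0.885. Its alignment name in the table lacked a tag that the other 22 carried. Libraries 1 and 2 of the stimulated wild-type-labelled cells with niacin had 0.187% and 0.217% of their counts on mitochondrial genes, against 0.605% in library 3 of that group. Library 1 of the unstimulated wild-type-labelled cells had 0.346%, against 0.937% and 0.802% in the others of its group, and leaving it out of the lists was chosen after seeing the data.

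Hcar2 encodes the G protein-coupled receptor that binds niacin. It lies on chromosome 5 at 123863570 to 123865499 and has 1 exon (ENSMUSG00000045502). Its counts went against the genotype labels. Of the 11 libraries labelled knockout, 10 held counts, 169 in total, with a mean of 0.673 ± 0.467 CPM (SD, n = 11). Of the 12 labelled wild type, 1 held a single count (0.00365 ± 0.0127 CPM, n = 12). A two-sided permutation test over libraries (100000 permutations) gave p = 2e-05. It treats the libraries as independent, which the labels do not settle.

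By group, the knockout-labelled libraries held 17, 26 and 7 counts unstimulated, 32 and 28 unstimulated with niacin, 4, 0 and 13 stimulated, and 16, 8 and 18 stimulated with niacin. The wild-type-labelled libraries held 1, 0 and 0 unstimulated and 0 in the other 9. Against the limit of 3 counts over a group at 0, Hcar2 was at least 32.4-fold higher in the knockout-labelled cells unstimulated with niacin (1.22 ± 0.201 CPM, n = 2), at least 13.4-fold higher stimulated with niacin (0.585 ± 0.222 CPM, n = 3) and at least 6.29-fold higher stimulated (0.244 ± 0.288 CPM, n = 3). Unstimulated, where the wild-type-labelled group held 1 count, the ratio was 51.1 (95% counting interval 9.16 to 2020). The library at 0 in the stimulated knockout-labelled group allows up to 0.13 CPM. By edgeR Hcar2 passed stimulated with niacin (adjusted p = 0.0443), but not unstimulated, stimulated or unstimulated with niacin (adjusted p = 0.409, 0.314 and 0.196). That 1 call was lost without library 1 or 2 of the wild-type-labelled or any of the knockout-labelled cells (adjusted p = 0.082 to 0.168). Averaged over the 4 conditions, its call was kept without any single library (adjusted p = 7.42e-05 to 0.00231). The part of the gene that was deleted is not given in the sources used here, so the counts do not settle whether the labels are exchanged or a transcript remains from the altered gene. All directions by genotype below are therefore those of the labels.

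**Figure D1:**
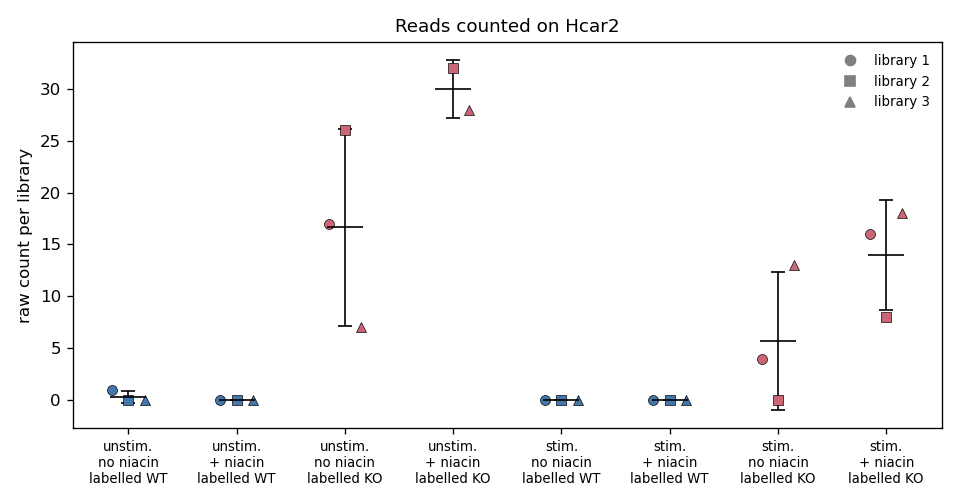
Raw counts of Hcar2 (y axis) in each of the 23 libraries (points) by group (x axis), with the group mean (bar) and SD (whiskers), wild-type-labelled libraries in blue and knockout-labelled ones in red. Counts lie in 10 of the 11 knockout-labelled libraries and in 1 of the 12 wild-type-labelled ones.

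The related receptor genes were close to the limit of detection. Hcar1, which encodes a lactate receptor and lies on chromosome 5 at 123876736 to 123880020, had 11 counts in library 3 of the stimulated wild-type-labelled cells with niacin (0.42 CPM) and 11 in library 3 of the knockout-labelled cells of that condition (0.434 CPM), and none in the other 21 libraries. Ffar2, a receptor gene for short-chain fatty acids on chromosome 7, lay between 0 and 2.19 CPM, and edgeR called it in no genotype or niacin comparison.

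The stimulation comparisons ask how activation through CD3 and CD28 changed the cells beside IL-2 alone. Il2ra, the inducible chain of the IL-2 receptor, rose from 253 ± 39.9 to 1362 ± 134 CPM in wild-type-labelled cells and from 224 ± 87.5 to 1556 ± 129 CPM in knockout-labelled cells (SD, n = 3 each). Ldha, which encodes the enzyme that makes lactate, rose from 1163 ± 221 to 9170 ± 359 CPM and from 989 ± 136 to 9972 ± 317 CPM. Il7r, the IL-7 receptor gene of resting T cells, fell from 651 ± 227 to 45.05 ± 6.5 CPM and from 530 ± 220 to 43.1 ± 2.98 CPM. Ldha and Il7r are outside the rule for naming genes. The class II gene H2-Ab1 rose from 7.55 ± 6.44 to 214 ± 15.7 CPM and from 6.61 ± 2.26 to 177 ± 21.3 CPM.

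With edgeR and Benjamini-Hochberg adjustment, 3946 genes rose and 3667 fell in wild-type-labelled cells, and 4256 rose and 4647 fell in knockout-labelled cells. With DESeq2, RLE factors or voom more genes fell than rose in wild-type-labelled cells too. The median log2 fold change of all genes was -0.07 and -0.13. In wild-type-labelled cells Ctla4 rose by 3.64 ± 0.23 (log2 ± SE, adjusted p = 1.47e-10) and Tnfrsf4, a costimulatory receptor gene, by 3.38 ± 0.16 (adjusted p = 1.92e-12). Tcf7, a transcription factor gene of naive cells, fell by 2.05 ± 0.16 (adjusted p = 3.56e-09). In knockout-labelled cells Ctla4 rose by 3.42 ± 0.23 (adjusted p = 2.96e-10), Tnfrsf4 by 3.22 ± 0.16 (adjusted p = 4.01e-12) and Gzmb by 3.67 ± 0.55 (adjusted p = 1.61e-05), and Tcf7 fell by 2.38 ± 0.16 (adjusted p = 4.29e-10). Foxp3, the regulatory T cell factor, fell in knockout-labelled cells by 2.14 ± 0.15 (adjusted p = 8.77e-10) and from 124 ± 13.2 to 40.23 ± 6.2 CPM in wild-type-labelled cells (adjusted p = 3.95e-08).

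The largest rises were from groups with no count. Smtnl2 reached 86.85 ± 9.02 CPM in wild-type-labelled and 62.6 ± 10 CPM in knockout-labelled cells, at least 2000-fold and at least 1360-fold higher. Vldlr, a lipoprotein receptor gene, was at least 950-fold and at least 864-fold higher, and Grin1 at least 249-fold and at least 198-fold. Scd1, which encodes a fatty acid desaturase, was at least 1080-fold higher in wild-type-labelled cells and rose by 9.39 ± 0.44 on the log2 scale in knockout-labelled cells (edgeR adjusted p = 2.33e-11). Among the largest falls, the gut-homing receptor gene Ccr9 fell by 6.72 ± 0.81 and by 7.56 ± 0.88 (edgeR adjusted p = 1.31e-06 and 7.29e-07), and St8sia6 fell by 5.93 ± 0.45 and by 7.13 ± 0.48 (adjusted p = 2.18e-09 and 4.18e-10). The chemokine gene Xcl1 fell by 7.52 ± 0.88 in wild-type-labelled cells (adjusted p = 9.7e-07). The ratio for the Th17 gene Il23r, higher in unstimulated than in stimulated wild-type-labelled cells, was 80.6 (95% counting interval 14.5 to 3180, from 1 count).

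The glycolysis and hypoxia response genes had the highest medians. Of 22 glycolysis genes, 20 rose in each genotype label (21 in each adjusted over the list alone), with median log2 fold changes of 3.04 and 3.11. Of 21 hypoxia genes, 19 rose in each label (19 and 19 adjusted over the list alone), with medians of 3.20 and 3.04. Aldoc, in the glycolysis list, rose by 7.38 ± 0.23 and Bnip3, in the hypoxia list, by 6.33 ± 0.22 in wild-type-labelled cells (edgeR adjusted p = 6.59e-15 and 2.6e-14). Camera with Benjamini-Hochberg adjustment over the lists gave adjusted p = 4.24e-20 and 5.88e-18 for glycolysis, and adjusted p = 0.0117 and 0.0186 with an estimated correlation. For hypoxia the values were 2.7e-17 and 1.46e-14, and adjusted p = 9.26e-05 and 0.000276 with an estimated correlation. Without library 3 of the unstimulated knockout-labelled cells, 18 hypoxia genes rose in that label.

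Biosynthetic genes rose as well. Of 25 cholesterol synthesis genes, 24 rose in each label (median 2.30 and 2.29), among them Sqle by 2.87 ± 0.15 and Hmgcs1 by 3.17 ± 0.18 in wild-type-labelled cells (edgeR adjusted p = 1.46e-11 and 3.18e-11). Of 30 genes of ATF4 and the integrated stress response, which includes amino acid synthesis, 27 rose and 1 fell in wild-type-labelled cells and 25 rose in knockout-labelled cells (median 1.99 and 2.13). Camera gave adjusted p = 1.73e-16 and 1.29e-15 for cholesterol synthesis (adjusted p = 0.033 and 0.0382 with an estimated correlation). It gave 1.6e-15 and 5.75e-14 for ATF4 (adjusted p = 0.0198 and 0.0296 with an estimated correlation). Of 36 nuclear genes of oxidative phosphorylation, 31 and 33 rose (median 0.83 and 0.96; camera adjusted p = 5.2e-09 and 6.63e-11, and adjusted p = 0.19 and 0.124 with an estimated correlation). Of 35 cell cycle genes, 29 and 34 rose (31 and 34 adjusted over the list alone; median 1.46 and 1.86; camera adjusted p = 1.98e-09 and 1.58e-11, and adjusted p = 0.375 and 0.355 with an estimated correlation).

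Genes of T cell state divided by function. Of 30 activation genes, 17 rose and 3 fell in each label (17 and 19 rose adjusted over the list alone), with medians of 1.65 and 1.88. Of 26 naive and quiescent genes, 21 and 22 fell and 1 rose (22 and 22 fell adjusted over the list alone), with medians of -1.09 and -1.29. Of 20 regulatory T cell genes, 12 and 13 rose and 5 fell in each label (13 and 13 rose adjusted over the list alone), with medians of 1.59 and 1.18. Foxp3 fell while Lrrc32, a surface protein gene of the same list, rose by 2.36 ± 0.19 in wild-type-labelled cells (edgeR adjusted p = 4.07e-09). Of 10 Th17 genes, 4 and 5 fell, with medians of -1.81 and -2.16. Camera gave adjusted p = 3.25e-05 and 8.61e-06 for activation, and adjusted p = 0.281 and 0.278 with an estimated correlation. For naive genes it gave 7.65e-09 and 5.76e-10, and adjusted p = 0.141 and 0.101 with an estimated correlation. For regulatory T cell genes it gave 0.00478 and 0.0278, and adjusted p = 0.257 and 0.355 with an estimated correlation. For Th17 genes it gave 0.0429 and 0.0295, and adjusted p = 0.436 and 0.407 with an estimated correlation.

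The helper lists with no camera call held changed genes in both directions. Of 16 Th1 genes, 6 rose and 7 fell in wild-type-labelled cells and 5 rose and 5 fell in knockout-labelled cells (median -0.36 and -0.17). The Th1 test in knockout-labelled cells leaned upward against its negative median and mean (camera adjusted p = 0.938). Of 12 Th2 genes, 5 rose and 1 fell and 5 rose and 3 fell (median 0.67 and 0.40, camera adjusted p = 0.164 and 0.193). Of 19 cytokine genes, 2 rose and 5 fell and 4 rose and 7 fell (median -0.68 and -0.35, camera adjusted p = 0.383 and 0.568).

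Of 22 NRF2 targets, 9 and 13 rose and 2 fell in each label (median 0.56 and 0.90; camera adjusted p = 0.0385 and 0.00893, and adjusted p = 0.375 and 0.278 with an estimated correlation). Of 30 interferon genes, 7 rose and 8 fell in wild-type-labelled and 13 rose and 4 fell in knockout-labelled cells, with medians of -0.09 and 0.16. The wild-type mean was 0.12, opposite in sign to that median, and camera gave adjusted p = 0.821 and 0.305. Without library 3 of the unstimulated knockout-labelled cells, 12 interferon genes rose and 7 fell in that label and the median was -0.14. Of 21 cAMP responsive genes, 11 rose and 4 fell and 7 rose and 5 fell (median 0.77 and 0.31, camera adjusted p = 0.141 and 0.59). Of 23 p53 targets, 7 rose and 6 fell and 8 rose and 5 fell (median 0.13 and 0.28, camera adjusted p = 0.9 and 0.568). Of 29 NAD metabolism genes, 6 rose and 9 fell and 7 rose and 7 fell (median 0.18 and 0.19), and the wild-type test leaned downward against its median (camera adjusted p = 0.855).

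Of 17 heat shock genes, 6 and 9 rose and 2 and 1 fell (median 0.35 and 0.44, camera adjusted p = 0.554 and 0.0934). Of 8 measured genes of the mitochondrial genome, 5 and 2 fell (median -1.14 and -1.01, camera adjusted p = 0.196 and 0.333). Without library 3 of the unstimulated knockout-labelled cells, 3 fell in that label. Without library 1 of the unstimulated wild-type-labelled cells, 6 fell in the other label, at a median of -1.52. Of 11 receptors and transporters of hydroxycarboxylic and short-chain fatty acids, 4 and 3 rose and 2 and 1 fell, with medians of 0.00 (camera adjusted p = 0.375 and 0.568).

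Markers of other cells were tested too. Of 12 NK and gamma delta T cell markers, 8 and 7 fell (8 and 8 adjusted over the list alone; median -2.66 and -2.28; camera adjusted p = 0.00167 and 0.0297, and adjusted p = 0.19 and 0.355 with an estimated correlation). Ncr1 was at least 68.7-fold lower in stimulated than in unstimulated wild-type-labelled cells (2.67 ± 2.61 CPM, n = 3), a bound that rests mostly on library 1 (5.68 CPM). Of 11 B cell markers, 2 fell in each label (0 and 1 adjusted over the list alone; median -0.78 and -1.12, camera adjusted p = 0.375 and 0.568). Of 14 myeloid and dendritic cell markers, 3 and 2 rose and 3 fell (median -0.75 and -1.39, camera adjusted p = 0.811 and 0.568). Neither of the 2 CD8 markers passed (median 0.23 and 0.33, camera adjusted p = 0.928 and 0.761), and the wild-type test leaned downward against its median. Of 5 erythroid and platelet markers, 2 rose and 1 fell in each label (median -0.72 and -0.93, mean 0.95 and 1.33, camera adjusted p = 0.811 and 0.767). Vldlr and Ncr1 lay beyond their lists' medians at their bounds as well as at their fitted values.

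**Figure D2:**
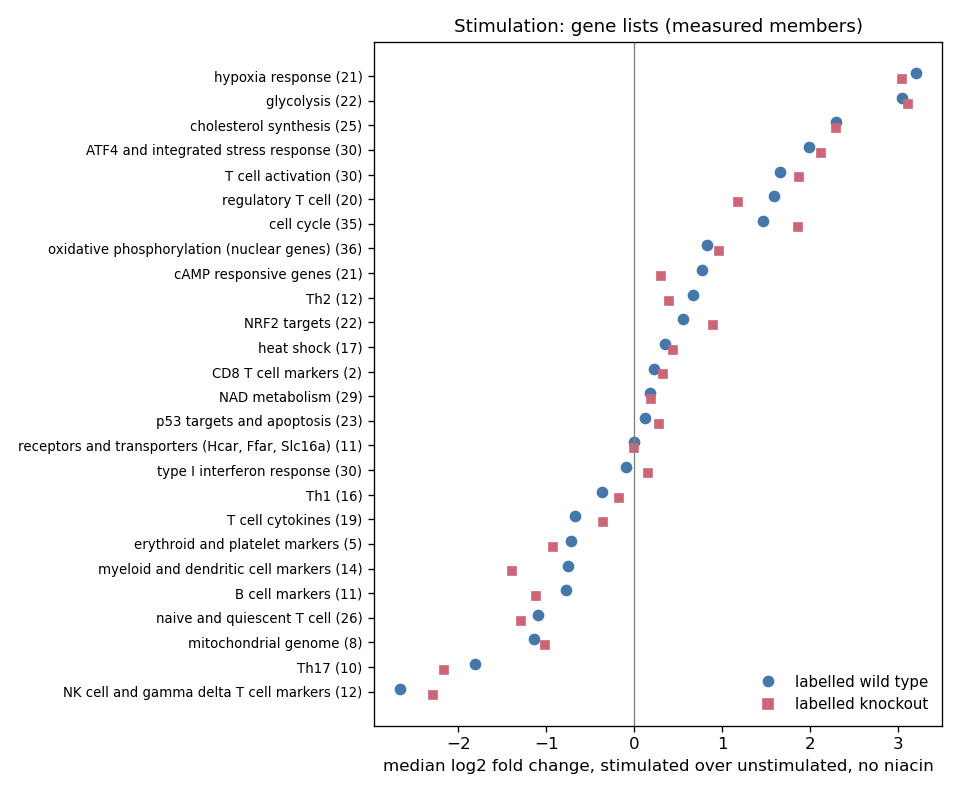
Median log2 fold change of stimulated over unstimulated cells without niacin (x axis) for the measured members of each of the 26 gene lists (y axis), with wild-type-labelled cells as circles and knockout-labelled cells as squares. The glycolysis medians lie at 3.04 and 3.11, the naive T cell medians at -1.09 and -1.29.

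The genotype comparisons ask which transcripts differ with the genotype label in each of the 4 conditions. Rab35, which encodes a small GTPase of endosome recycling, was higher with the knockout label in all 4, for example at 183 ± 76.3 against 40.14 ± 7.33 CPM unstimulated and 185 ± 58.2 against 47.55 ± 6.25 CPM stimulated (SD, n = 3 each). It lies on chromosome 5, as Hcar2 does, at 115631908 to 115647736. For Rab35 edgeR gave log2 fold changes of 2.19 ± 0.27 unstimulated, 1.96 ± 0.27 stimulated, 2.18 ± 0.29 unstimulated with niacin and 1.83 ± 0.27 stimulated with niacin (SE; Benjamini-Hochberg adjusted p = 0.000199, 0.000943, 0.000592 and 0.00185). Its call was kept without any single library in each condition, but was lost unstimulated with only the compared groups in the fit (adjusted p = 0.294).

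Also called in all 4 conditions were 4 annotated copies of Rplp0, a gene of the large ribosomal subunit on chromosome 5 at 115559467 to 115563727. Gm8730, Gm9625, Gm14165 and Rplp0-ps1 were 98.7%, 97.4%, 97.2% and 94.2% identical to the Rplp0 transcript and lie on chromosomes 8, 13, 2 and 3. They fall outside the rule for naming genes and were named after their values were seen. Reads can be shared between Rplp0 and its copies, so the single values are uncertain. The summed level of the called copies, Gm5948 (86.1% identical) included, was 297 ± 155 CPM with the knockout label against 4.01 ± 0.542 CPM with the wild-type label unstimulated, and 589 ± 199 against 10.52 ± 0.649 CPM stimulated. Rplp0 itself was lower with the knockout label, at 578 ± 185 against 918 ± 105 CPM unstimulated and 1151 ± 366 against 2204 ± 118 CPM stimulated.

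**Figure D3:**
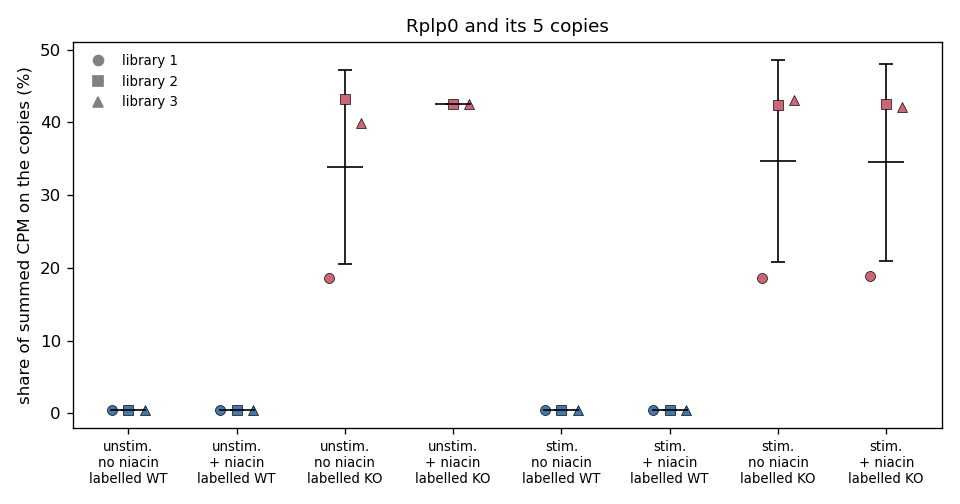
Share of the summed CPM of Rplp0 and its 5 called copies that lay on the copies (y axis, percent) in each library (points) by group (x axis), with group mean (bar) and SD (whiskers). Wild-type-labelled libraries lie at 0.42% to 0.52%, knockout-labelled libraries numbered 1 at 18.6% to 18.8% and the other knockout-labelled libraries at 39.9% to 43.1%.

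Few transcripts differed by label in unstimulated cells. Without niacin edgeR called 6 genes higher and 1 lower with the knockout label, and with niacin 5 and 1 (1760 and 166 genes at an unadjusted p under 0.05, where 844 would be expected if no gene differed, so that the second number lies below it). Hip1r, an adaptor of endocytosis on chromosome 5, was higher unstimulated by 1.43 ± 0.25 (adjusted p = 0.0243). Its call was lost without library 1, 2 or 3 of the wild-type-labelled or library 3 of the knockout-labelled cells (adjusted p = 0.116 to 0.255). Without library 2 of the knockout-labelled cells 342 genes were called unstimulated. With niacin, leaving out any 1 of the libraries compared gave 6 or 7.

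Regulatory T cell genes leaned upward in unstimulated knockout-labelled cells. With niacin 17 of 20 had positive log2 fold changes, with a median of 0.31 (0 passed over all genes and 2 rose adjusted over the list alone; camera adjusted p = 5.98e-10, and adjusted p = 0.0276 with an estimated correlation). Without niacin the median was 0.22 (0 passed over all genes, 4 rose adjusted over the list alone; camera adjusted p = 0.00413, and adjusted p = 0.469 with an estimated correlation), and 3 rose adjusted over the list alone without library 3 of the knockout-labelled cells. Foxp3 was at 176 ± 15.4 against 124 ± 13.2 CPM without niacin and at 206 ± 6.88 (n = 2) against 143 ± 2.79 CPM with niacin. Interferon genes had medians of -0.45 without niacin and -0.24 with it (0 and 1 fell adjusted over the list alone; camera adjusted p = 8.01e-07 and 0.000277, and adjusted p = 0.697 and 0.868 with an estimated correlation). Cholesterol synthesis genes had medians of -0.20 and -0.18 (camera adjusted p = 0.0207 and 0.000577, and adjusted p = 0.829 and 0.868 with an estimated correlation). The medians without niacin were -0.28 for interferon and -0.13 for cholesterol synthesis genes when library 3 of the knockout-labelled cells was left out. Without library 1 of the wild-type-labelled cells the regulatory T cell median without niacin was 0.39, with 0 adjusted over the list alone, and the cholesterol median -0.11. With niacin the cell cycle list had a median of -0.36 (camera adjusted p = 0.00114, and adjusted p = 0.868 with an estimated correlation).

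In stimulated cells without niacin 8 genes were higher and 11 lower with the knockout label (1426 at an unadjusted p under 0.05). The balance was not stable, with 5 or 6 higher and 1 to 3 lower without any 1 of 4 of the libraries compared. Cd7, a surface receptor gene of T cells, was lower at 3.51 ± 0.69 against 9.07 ± 1.87 CPM (log2 fold change -1.37 ± 0.23, edgeR adjusted p = 0.0204). The call of Cd7 was lost without library 1 or 2 of the wild-type-labelled or library 2 or 3 of the knockout-labelled cells (adjusted p = 0.0608 to 0.244). Pdlim4, Nipsnap2, Ramp1 and Tmco3 were lower, with log2 fold changes of -1.22, -0.98, -0.90 and -0.65, and Erp29, an endoplasmic reticulum chaperone gene, was higher by 0.63 (adjusted p = 0.0464 each). Each of these 5 calls was lost without library 1 or 2 of the wild-type-labelled or library 2 or 3 of the knockout-labelled cells, with adjusted p of up to 0.312 for Pdlim4, 0.244 for Nipsnap2, 0.333 for Ramp1, 0.333 for Tmco3 and 0.312 for Erp29. Nipsnap2 and Erp29 lie within 20 Mb of Hcar2 on chromosome 5. Without library 1 or 2 of the wild-type-labelled cells 6 and 8 genes were called, and without library 2 or 3 of the knockout-labelled cells 7 and 7. Leaving library 3 of the unstimulated knockout-labelled cells out of the shared fit, chosen after seeing the data, gave 35.

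Naive and quiescent genes leaned downward in stimulated knockout-labelled cells, with a median of -0.28 and 24 of 26 negative (0 passed over all genes, 6 fell adjusted over the list alone; camera adjusted p = 1.6e-05, and adjusted p = 0.517 with an estimated correlation). Hypoxia genes had a median of -0.28 (2 fell adjusted over the list alone; camera adjusted p = 0.0101, and adjusted p = 0.369 with an estimated correlation). Activation, cell cycle, oxidative phosphorylation, ATF4, NRF2 and heat shock lists had medians of 0.15, 0.15, 0.06, 0.19, 0.21 and 0.23 (camera adjusted p = 0.0209, 0.0186, 0.0231, 0.0239, 0.0209 and 0.0231). They had adjusted p = 0.771, 0.803, 0.771, 0.771, 0.608 and 0.718 with an estimated correlation.

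With stimulation and niacin together 97 genes were higher and 146 lower with the knockout label (3273 at an unadjusted p under 0.05). The excess of lower genes was not stable: 720 were higher and 304 lower without library 3 of the wild-type-labelled cells, 911 and 856 without library 3 of the unstimulated knockout-labelled cells, and 1876 and 1527 with voom. Cd7 was lower at 4.03 ± 0.49 against 12.71 ± 2.85 CPM (log2 fold change -1.65 ± 0.23, edgeR adjusted p = 0.00144). Dzip1, the glycolytic Aldoc and the stress factor gene Ddit3 were lower by log2 fold changes of -1.80 ± 0.30, -1.07 ± 0.17 and -1.02 ± 0.16 (adjusted p = 0.00513, 0.0045 and 0.00317). These calls and that of Rab35 were kept without any single library, and 15 of the 21 named genes lost theirs without at least 1. Tfrc, the transferrin receptor gene, was at 662 ± 47.5 against 219 ± 106 CPM (edgeR adjusted p = 0.0466), a call lost without library 1 or 2 of the wild-type-labelled or any of the knockout-labelled cells (adjusted p = 0.0829 to 0.237). Txnip, an inhibitor of glucose uptake, was lower by a log2 fold change of -0.96 ± 0.18 (adjusted p = 0.013), a call lost without library 1 or 2 of the wild-type-labelled or 2 or 3 of the knockout-labelled cells (adjusted p = 0.0539 to 0.0835).

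The number of calls in that condition moved with single libraries. Without library 1, 2 or 3 of the wild-type-labelled cells 42, 53 and 1024 genes were called, and without library 1, 2 or 3 of the knockout-labelled cells 110, 49 and 39. Leaving library 3 of the unstimulated knockout-labelled cells out of the shared fit gave 1767. Without both wild-type-labelled libraries of low mitochondrial share 7 genes were called, a choice made after seeing the data. That left 1 library of the group, assumed to vary like the other groups. The calls of Rab35, Cd7, Dzip1 and Ddit3 were lost with log2 fold changes of 1.83 ± 0.42, -1.39 ± 0.30, -1.65 ± 0.39 and -0.83 ± 0.22 (adjusted p = 0.187, 0.158, 0.187 and 0.231), each less than the SE of that fit from its value with all libraries. The call of Aldoc was lost as well, at -1.003 ± 0.24 (adjusted p = 0.188). For each of the 5 the SE was larger than with all libraries and, apart from Rab35, the fold was smaller.

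The 8 measured genes of the mitochondrial genome had a median of 1.10 (0 passed over all genes, 6 rose adjusted over the list alone; camera adjusted p = 1.33e-05, and adjusted p = 0.535 with an estimated correlation), and without the libraries of low mitochondrial share the median was 0.26 and none rose adjusted over the list alone. Naive genes had a median of -0.33 (3 fell over all genes, 4 adjusted over the list alone; camera adjusted p = 0.00116, and adjusted p = 0.759 with an estimated correlation). Glycolysis genes had a median of -0.27 (1 fell over all genes, 1 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.00159, and adjusted p = 0.759 with an estimated correlation). Heat shock genes had a median of 0.33 (1 rose over all genes, 7 adjusted over the list alone; camera adjusted p = 0.000408, and adjusted p = 0.403 with an estimated correlation). Cell cycle, oxidative phosphorylation and hypoxia lists had medians of 0.31, 0.15 and -0.27 (camera adjusted p = 0.00116, 0.0138 and 0.0114, and adjusted p = 0.949, 0.91 and 0.403 with an estimated correlation). Without both libraries the hypoxia median was -0.48, and the naive, glycolysis and heat shock medians were -0.37, -0.19 and 0.40. None of these genes then passed over all genes, with 1 library left in the group. The folds of Txnip, Pik3ip1 and Hsph1, called before, were -0.86 ± 0.26, -1.04 ± 0.36 and 0.88 ± 0.32, against -0.96 ± 0.18, -1.23 ± 0.26 and 1.05 ± 0.22. That of Ccr7, the other naive gene called before, was -0.548 ± 0.225, against -0.728 ± 0.159. For these genes the lost calls do not show that the 2 libraries caused them.

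The niacin comparisons ask which transcripts 5 mM niacin changed in each background. The interferon-induced gene Ifit3 was at 20.98 ± 11.4 CPM with niacin against 86.47 ± 13.7 CPM without it in unstimulated wild-type-labelled cells (n = 3 each) and at 13.02 ± 1.09 (n = 2) against 41.8 ± 21.8 CPM in unstimulated knockout-labelled cells. Irf7, a transcription factor gene of the same response, was at 103 ± 13.6 against 151 ± 22.4 CPM in stimulated wild-type-labelled cells and at 63.2 ± 25.8 against 153 ± 30.3 CPM in stimulated knockout-labelled cells. Neither gene passed adjustment over all genes in a single background.

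By edgeR with Benjamini-Hochberg adjustment, niacin changed 0 genes in unstimulated wild-type-labelled, unstimulated knockout-labelled and stimulated wild-type-labelled cells, where 457, 1343 and 1682 genes had an unadjusted p under 0.05. DESeq2 called 14, 7 and 42 there and voom with sample quality weights 286, 4 and 1828. Without library 3 of the unstimulated knockout-labelled cells 16 were called in unstimulated wild-type-labelled cells, without library 2 of unstimulated knockout-labelled cells with niacin 1 was called in that background, and without library 3 of stimulated wild-type-labelled cells with niacin 560. In stimulated knockout-labelled cells 1 gene rose, Gm26789 (adjusted p = 0.0269; 882 at an unadjusted p under 0.05; DESeq2 11, voom 8). Gm26789 is outside the rule for naming genes and is an antisense gene, so its counts are uncertain. Without library 1 or 3 of the stimulated knockout-labelled cells or library 2 or 3 of those with niacin no gene was called. Without library 2 of the stimulated knockout-labelled cells 1 other gene was called and Gm26789 was not, and without library 1 of those with niacin 2 were called.

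Interferon response genes were lower with niacin as a group in each background. Of 30, 29, 28, 30 and 30 had negative log2 fold changes in unstimulated wild-type-labelled, unstimulated knockout-labelled, stimulated wild-type-labelled and stimulated knockout-labelled cells, with medians of -0.89, -0.70, -1.02 and -0.91. None passed over all genes, and 19, 12, 22 and 22 fell adjusted over the list alone. Camera gave adjusted p = 5.75e-32, 6.68e-10, 4.71e-17 and 1.16e-30, and adjusted p = 0.0926, 0.848, 0.611 and 0.107 with an estimated correlation. Without library 3 of the unstimulated knockout-labelled cells 19 fell adjusted over the list alone in that label. Without libraries 1 and 2 of the stimulated wild-type-labelled cells with niacin 1 did there, at a median of -0.88.

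The mean log2 CPM of the 30 genes was lower with niacin, by a difference of -0.918 averaged over the 4 backgrounds. An exact permutation of niacin within the backgrounds (80000 arrangements, two-sided) gave p = 7.5e-05 and a Benjamini-Hochberg adjusted p of 0.00195 over the 26 lists. By the same exact permutation the next lists were the cAMP responsive genes (-0.184, p = 0.0219, adjusted p = 0.199) and the hypoxia genes (-0.111, p = 0.0229, adjusted p = 0.199). Leaving out each library in turn gave differences from -1.001 without library 3 of the unstimulated knockout-labelled cells to -0.849 without library 3 of the stimulated knockout-labelled cells with niacin. Without both libraries of low mitochondrial share it was -0.88 (exact p = 0.000312).

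**Figure D4:**
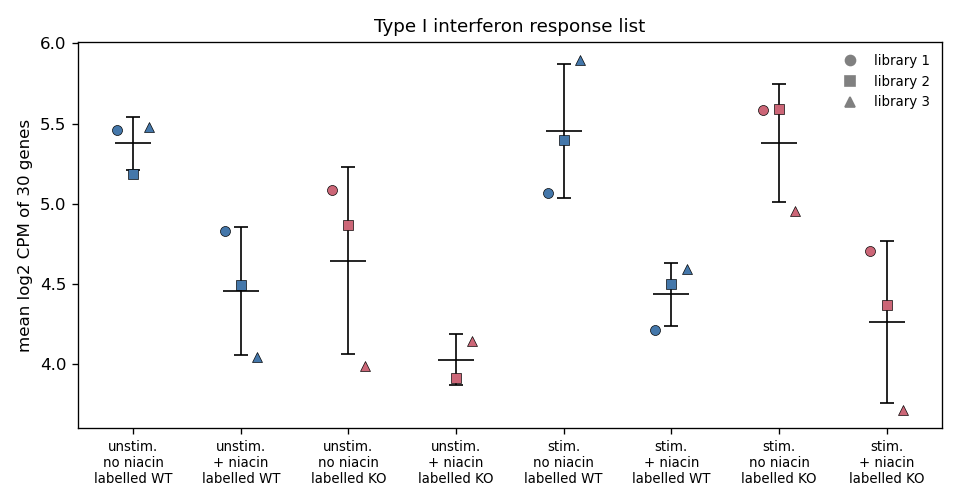
Mean log2 CPM of the 30 interferon response genes (y axis) in each library (points) by group (x axis), with the group mean (bar) and SD (whiskers). The average over the 4 backgrounds is -0.918 for niacin against no niacin.

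The niacin calls of the other lists were lost with an estimated correlation too. In unstimulated wild-type-labelled cells the cell cycle, glycolysis and oxidative phosphorylation lists had medians of -0.20, -0.21 and -0.16 (camera adjusted p = 4.21e-05, 2.05e-05 and 9.85e-06, and adjusted p = 0.644, 0.514 and 0.565 with an estimated correlation). The mitochondrial genome and heat shock lists had medians of 0.22 and -0.07 (camera adjusted p = 0.0363 each, and adjusted p = 0.644 and 0.565 with an estimated correlation). Without library 1 of those cells without niacin the 5 medians were 0.09, -0.06, -0.10, -0.10 and -0.14, so the cell cycle and mitochondrial medians changed sign. In unstimulated knockout-labelled cells the cell cycle, ATF4 and cAMP lists had medians of -0.29, -0.27 and -0.35 (camera adjusted p = 0.0078, 0.0213 and 0.0213, and adjusted p = 0.949, 0.848 and 0.848 with an estimated correlation). The ATF4 and cAMP medians were -0.10 and -0.05 when library 3 of those cells without niacin was left out. In stimulated wild-type-labelled cells the mitochondrial genome had a median of -0.94 (6 of 8 fell adjusted over the list alone; camera adjusted p = 9.48e-07, and adjusted p = 0.611 with an estimated correlation), and without libraries 1 and 2, in which the mitochondrial share was low, the median was -0.04. In stimulated knockout-labelled cells the ATF4 list had a median of -0.21 (camera adjusted p = 0.00396, and adjusted p = 0.66 with an estimated correlation).

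Whether effects differed by genotype label was tested directly. For stimulation 1 gene passed, Nrn1, which encodes a small membrane-anchored protein. It rose from 6.76 ± 0.687 to 37.99 ± 2.28 CPM in wild-type-labelled cells and from 13.03 ± 3.16 to 22.03 ± 2.86 CPM in knockout-labelled cells, a difference in log2 fold change of -1.72 ± 0.25 (edgeR adjusted p = 0.0156; 1773 genes at an unadjusted p under 0.05). The call was lost without library 1 or 2 of the unstimulated wild-type-labelled, library 1 of the unstimulated knockout-labelled, library 1 or 2 of the stimulated wild-type-labelled or library 2 or 3 of the stimulated knockout-labelled cells (adjusted p = 0.0516 to 0.11). For niacin in unstimulated cells Fzd7 passed (adjusted p = 0.0444; 326 at an unadjusted p under 0.05). It is outside the rule for naming genes, averaged at most 0.506 CPM in the 4 groups compared, and had no count in unstimulated knockout-labelled cells. For niacin in stimulated cells 0 genes passed with edgeR (874 at an unadjusted p under 0.05), DESeq2 called 5 and voom 185. A niacin or stimulation effect past its threshold with one label and not the other is therefore not shown to differ. For Nrn1 the test passed, but its call depended on single libraries.

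Across 16882 genes, the log2 fold changes of stimulation in wild-type-labelled and knockout-labelled cells, which share no library, had Pearson r = 0.79 and Spearman rho = 0.83. Those of niacin had r = 0.17 and rho = 0.24 in unstimulated cells and r = 0.02 and rho = 0.11 in stimulated cells. Over the 9743 genes of at least 5 CPM, r was 0.92, 0.35 and 0.30. Genes are not independent replicates, so no p is given.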

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

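The splits of libraries given in this part were chosen only after the counts of genes they test had been seen. Effects of stimulation or niacin that differed between the genotype labels drew attention here, since the difference itself passed its test.

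Nrn1, a membrane-anchored protein gene, responded less to stimulation in knockout-labelled cells, with a difference in log2 fold change of -1.72 ± 0.25 (SE, edgeR adjusted p = 0.0156). In all 3 stimulated wild-type-labelled libraries it lay above the stimulated knockout-labelled ones (37.99 ± 2.28 against 22.03 ± 2.86 CPM). Of 100 splits of the libraries, 7 called at least as many genes as the real 1, and the highest other called 12, so a chance split was not excluded for this count. In that highest split the label was exchanged in unstimulated cells alone, so genes differing by label in both conditions enter its 12. The adjusted p was 0.0549 without library 1 of the unstimulated knockout-labelled cells, 0.0516 without library 1 of the stimulated wild-type-labelled cells and at most 0.11 without any other library.

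Fzd7, a Wnt receptor gene, differed between labels in its response to niacin in unstimulated cells, by a fitted 10.54 on the log2 scale (edgeR adjusted p = 0.0444). It lay at 0.444 ± 0.19 CPM without and 0.0251 ± 0.0221 CPM with niacin in wild-type-labelled cells, and at 0 without and 0.506 ± 0.595 CPM with niacin (n = 2) in knockout-labelled cells. The fitted value rests on groups at or near 0 and is no bound. No gene was called without any 1 of 10 of the 11 libraries compared, and Fzd7 is not read further.

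Lists whose stimulation response differed by label with the preset correlation were the naive and quiescent genes (median of the difference -0.28, camera adjusted p = 0.00942), the cell cycle (0.38, 0.0023), oxidative phosphorylation (0.20, 0.0029), the interferon response (0.36, 0.0023), cholesterol synthesis (0.18, 0.0409), cAMP responsive genes (-0.37, 0.0263) and heat shock (0.32, 0.011). Without library 3 of the unstimulated knockout-labelled cells the interferon, cholesterol and cAMP medians were 0.22, 0.10 and -0.22. Without library 1 of the unstimulated wild-type-labelled cells, left out after seeing the data, the cell cycle and cAMP medians were 0.13 and -0.59. None of the lists held: adjusted p = 0.716 with an estimated correlation for 6 of them and 0.733 for the cell cycle. For niacin in unstimulated cells the NK and gamma delta T cell markers differed (median 0.64, camera adjusted p = 0.0175, and adjusted p = 0.978 with an estimated correlation).

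For niacin in stimulated cells the mitochondrial genome differed (median 0.83, camera adjusted p = 0.000172), as did the ATF4 genes (median -0.26, camera adjusted p = 0.00272), with adjusted p = 0.947 for both with an estimated correlation. The mitochondrial difference goes with the low mitochondrial share of libraries 1 and 2 of the stimulated wild-type-labelled cells with niacin, 0.187% and 0.217%. Without both libraries the medians were -0.07 for the mitochondrial genome and -0.12 for the ATF4 genes. No single gene passed this test, so a count of splits with at least as many decides nothing here. The highest of the other 99 splits called 335 genes, which points to a structure among these libraries whose cause was not tested. In that split the libraries with niacin stayed divided by label and those without niacin were mixed.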

How the results depend on the processing

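Leaving library 3 of the unstimulated knockout-labelled cells out of comparisons it was not part of, leaving out libraries 1 and 2 of the stimulated wild-type-labelled cells with niacin together, and all alternatives for both averages were chosen only after the results had been seen. Comparisons are named here by genotype, niacin or stimulation and by cells. For the counts of genes given in this part the cause of a change was not tested, apart from fewer libraries or groups in the fit.

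Direction was compared only for results that passed the threshold in the main fit. Of 309 results of named genes, 308 kept their side of the threshold with DESeq2 and 308 with RLE factors. With no filter 305 did, with the replicate block 302 and with voom 305, and 246 of 254 did with only the compared groups. Of 390 list results, 368, 388, 376, 378 and 344 did, and 320 of 338 with only the compared groups. Over the fits that leave out 1 library, 2328 of 2506 gene results did, and 177 lost their call. In these fits no called gene or list changed direction. Lists were not fitted without each library in turn, and some list medians changed sign without a library that stands apart. With only the compared groups in the fit Rab35 lost its call in unstimulated cells (adjusted p = 0.294).

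By genotype, in unstimulated, stimulated, unstimulated with niacin and stimulated with niacin, DESeq2 called 22, 102, 18 and 1122 genes against 7, 19, 6 and 243. In stimulated cells it had 22 higher and 80 lower, and in unstimulated cells with niacin 12 and 6. With no filter 673, 208, 23 and 1138 were called. With voom and quality weights 169, 31 and 3403 were called in the last 3, and with only the compared groups 434 in the last. Without libraries 1 and 2 of the stimulated wild-type-labelled cells with niacin 7 were called in the last.

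By niacin, in unstimulated wild-type-labelled, unstimulated knockout-labelled, stimulated wild-type-labelled and stimulated knockout-labelled cells, DESeq2 called 14, 7, 42 and 11 against 0, 0, 0 and 1. With no filter 62, 418, 344 and 101 were called, and with voom 286, 4, 1828 and 8. In stimulated knockout-labelled cells 0 were called with the replicate block and with only the compared groups. By stimulation, only the compared groups gave 5880 against 8903 in knockout-labelled cells.

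For effects differing by genotype, of stimulation, of niacin in unstimulated and of niacin in stimulated cells, the counts were 1, 1 and 0. DESeq2 gave 6 for the first and 5 for the last. No filter gave 457, 85 and 80. Voom gave 0 for the middle and 185 for the last. Only the compared groups gave 0 for the first and 0 for the middle, and the replicate block gave 0 for the middle. For the averages of niacin and genotype, against 26 and 55, DESeq2 called 109 (29 higher and 80 lower) and 257, no filter 200 and 347, and voom 355 and 843. Without libraries 1 and 2 of the stimulated wild-type-labelled cells with niacin 14 and 26 were called.

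Leaving out each library in turn, and library 3 of the unstimulated knockout-labelled cells also from comparisons it was not part of, gave 6 to 342 (genotype, unstimulated), 6 to 35 (stimulated), 6 to 8 (unstimulated with niacin) and 39 to 1767 (stimulated with niacin). For niacin it gave 0 to 16, 0 to 1, 0 to 560 and 0 to 2, and for stimulation 6085 to 8851 and 7761 to 9144. For the differing effects it gave 0 to 2, 0 to 1 and 0 to 1, and for the averages 11 to 98 and 20 to 154. In the fits with 1 library of unstimulated knockout-labelled or stimulated wild-type-labelled cells with niacin, that library was assumed to vary like the other groups.

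The correlations of effects across all genes between labels were 0.1675 for niacin unstimulated, 0.0164 for niacin stimulated and 0.7903 for stimulation. Without single libraries they ran from 0.0797 to 0.2105, from -3e-04 to 0.0228 and from 0.7412 to 0.8009. The all-gene value for niacin stimulated changed sign without library 1 of the stimulated knockout-labelled cells (-3e-04), from a value near 0. Over genes of at least 5 CPM the values were 0.3532, 0.2999 and 0.9221, and no library was left out there.

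Whether the replicate numbers pair the libraries was not settled. Across genes, only 4 of 28 pairs of same-numbered libraries had a correlation of their deviations from the group mean over 0.1 (-0.18 to 0.289). Of 23 libraries, 9 correlated best with their own number. Knockout-labelled libraries numbered 1 did share a low part of Rplp0 reads on its copies. The replicate block ended the calls of Gm26789, Fzd7 and 7 named genes: Erp29, Nipsnap2 and Pdlim4 by genotype in stimulated cells, Hcar2 and Tfrc by genotype in stimulated cells with niacin, and Foxp3 and Rnf32 in the averages of niacin and genotype, these 7 at an adjusted p between 0.05 and 0.08. Apart from the counts of Gm26789 and Fzd7 it moved none by over 1.5 times.

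Depth limits genes such as Hcar2: a count of 0 allowed up to 0.0997 to 0.145 CPM per library. Counts varied between replicates by 9.85 to 260 times the counting error as chi-square per degree of freedom, as 1 value over all genes for each pair.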

Other observations

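The comparisons of averages, the permutation of list levels, the numbers and shares of Rplp0 copies, the pairs of libraries left out, the comparison of summed marker levels and the splits within single conditions were chosen only after the results they test had been seen. The tests of a strain variant, of depth and of the splits for both averages were set before their results.

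Averaged over the 4 backgrounds, niacin lowered interferon-induced genes. Ifit3 fell by 1.64 ± 0.24 on the log2 scale, Isg15, which encodes a ubiquitin-like modifier, by 1.23 ± 0.18 and Irf7 by 0.94 ± 0.13 (SE; edgeR adjusted p = 0.00277, 0.00288 and 0.00277). Gbp10, an interferon-induced GTPase gene, fell by 1.27 ± 0.20 (adjusted p = 0.00421). These 4 calls were kept without any single library. Foxp3 rose by 0.38 ± 0.08 (adjusted p = 0.0338), a call lost without any 1 of 16 libraries (adjusted p of up to 0.157). In all, 3 genes rose and 23 fell, and 18 of 30 interferon genes fell (28 adjusted over the list alone; median -0.92; camera adjusted p = 9.65e-60, and adjusted p = 0.00686 with an estimated correlation). Without library 2 or 3 of the unstimulated knockout-labelled cells with niacin 8 and 11 of the interferon genes fell, and without both libraries of low mitochondrial share 10 did. Of the other lists, the NAD metabolism genes had 3 members that fell adjusted over the list alone. As a whole that list did not pass the exact permutation of niacin (difference -0.068, p = 0.0767, adjusted p = 0.498).

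The number of genes in that average was 11 and 16 without library 2 or 3 of the unstimulated knockout-labelled cells with niacin. It was 49, 98 and 41 without library 1 of the unstimulated wild-type-labelled cells with niacin, library 3 of the unstimulated knockout-labelled cells or library 3 of the stimulated wild-type-labelled cells with niacin. Of 100 splits of niacin within the backgrounds, only the real one called 26 genes or more, and the highest other called 17. The share of splits with as many genes was under 0.05. This average was chosen after the data had been examined, so that share does not exclude chance.

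Averaged over the 4 conditions, 17 genes were higher and 38 lower with the knockout label. Vsig10, an immunoglobulin-domain gene, was higher by 2.12 ± 0.31 and Gpr83, a receptor gene of regulatory T cells, by 0.46 ± 0.07 (edgeR adjusted p = 0.000954 and 0.00211). Nipsnap2 was lower, at -1.05 ± 0.10, as were Rplp0 at -1.02 ± 0.12 and Cd7 at -0.80 ± 0.12 (adjusted p = 1.21e-06, 5.24e-05 and 0.000975). Of these, Nipsnap2 and Rplp0 lie within 20 Mb of Hcar2 on chromosome 5. Oasl2, an interferon-induced gene, was lower at -3.13 ± 0.62 (adjusted p = 0.0245), a call lost without library 3 of the unstimulated wild-type-labelled cells, library 2 or 3 of the unstimulated knockout-labelled cells with niacin, library 3 of the stimulated knockout-labelled cells or library 2 or 3 of the stimulated knockout-labelled cells with niacin (adjusted p of up to 0.172). Without library 2 or 3 of the unstimulated knockout-labelled cells with niacin 36 genes (18 higher and 18 lower) and 20 genes (12 higher and 8 lower) were called, so the excess of lower genes was not stable. Without library 1 of the unstimulated wild-type-labelled cells with niacin or library 2 or 3 of the unstimulated knockout-labelled cells 85, 86 and 154 were. Of 100 splits of the labels within the conditions, only the real one called 55 or more and the highest other called 22. The share of splits with as many genes was under 0.05. This average too was chosen after the data had been examined, so that share does not exclude chance. The splits also treat same-numbered libraries of different conditions as independent, which was not settled.

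Glycolysis genes had a median of -0.18 in that average (0 over all genes, 8 fell adjusted over the list alone; camera adjusted p = 2.75e-05, and adjusted p = 0.324 with an estimated correlation), and none fell without both libraries of low mitochondrial share. Naive genes had a median of -0.14 (1 fell over all genes, 8 adjusted over the list alone; camera adjusted p = 2.68e-05, and adjusted p = 0.324 with an estimated correlation). Regulatory T cell genes had a median of 0.16 (1 rose over all genes, 3 adjusted over the list alone; camera adjusted p = 0.000216, and adjusted p = 0.301 with an estimated correlation), and of 0.10 without library 3 of the unstimulated knockout-labelled cells. By exact permutation of the label within conditions, only the receptor and transporter list, which holds Hcar2, passed (difference 0.338, Benjamini-Hochberg adjusted p = 0.00325). That test treats all libraries as independent, and whether replicate numbers pair them was not settled. Where same-numbered libraries share an animal, its p would be too small. Hcar2 itself differed by label and the list was not tested without it, so the pass may restate that difference.

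Rab35 and the other genes reported for all 4 genotype comparisons lay near Hcar2 or were copies of Rplp0, which is itself near Hcar2 on chromosome 5. A strain variant around Hcar2 may explain this: of the calls, 3 of 7, 5 of 19, 2 of 6 and 12 of 243 lay within 20 Mb of Hcar2. That stretch held 552 of the uncalled genes, against 15567 elsewhere, so the last of these counts is close to the share of all genes. The bound set beforehand for uncalled genes of that stretch was missed, as 8 of 123 other stretches had as high a share at an unadjusted p under 0.05. The share was 12.3% (95% interval 9.69% to 15.4%), against 12.7% for the top 5% of stretches and 8.68% elsewhere, so the interval includes the bound. That the interval counts was decided only after this value had been seen, and the explanation stays open. A difference in the breeding of the animals was not tested.

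Reads of Rplp0 counted on its copies could explain the copies and the lower Rplp0 together. The sum of both left 11.4%, 35.2%, 37.2% and 52.8% of the log2 difference of Rplp0 in the 4 conditions. The bound of 50% was missed in stimulated cells with niacin, by less than the jackknife SD of 8.3, so that part stays open.

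Among knockout-labelled cells, the libraries numbered 1 had 18.6%, 18.7% and 18.8% of the reads on copies, against 39.9% to 43.1% in the others (27 arrangements, exact p = 0.037, the smallest possible). These libraries were picked after their low shares had been seen, so that p was fixed in advance and adds no support. A candidate explanation is 1 altered and 1 reference copy near Rplp0 in the libraries numbered 1, and the largest distance from the midpoint it predicts was 2.6 percentage points. A single mislabelled library is argued against, since 0 libraries lay inside the range of the other label (lowest knockout-labelled 154 CPM, highest wild-type-labelled 14.2 CPM). Both labels exchanged in every library cannot be told apart from a transcript remaining in the altered gene, as 10 knockout-labelled libraries held Hcar2 counts, which either would give.

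Genotype calls were most numerous with stimulation and niacin, 243 against 7, 19 and 6. A difference in depth is argued against: with all libraries thinned to 13205565 counts 243 genes were called, against 7, 12 and 6. Whether the 2 libraries that stand apart in mitochondrial share account for the count stays open. Without them 7 genes were called, but 1 library of that group then remained, assumed to vary like the other groups. The bound set for that was missed, since other pairs left 64, 43, 129, 6 and 6, so their part cannot be told apart from that of having fewer libraries. Niacin acting differently by genotype also stays open, as 0 genes passed the test of that difference.

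Splits of the libraries within single conditions numbered 10 each, too few for a share under 0.05. The genotype comparisons called 7, 19 and 243 genes unstimulated, stimulated and stimulated with niacin, and the highest other splits 1, 1 and 0. The niacin comparisons called 0, 0 and 1 in unstimulated wild-type-labelled, stimulated wild-type-labelled and stimulated knockout-labelled cells, and the highest other splits 1, 0 and 1. The stimulation comparisons called 7613 and 8903, and the highest other splits 0 and 1. Each other split mixed stimulated and unstimulated libraries on both sides, which widens the spread within a side. Their low counts therefore add no support. Splits with at least as many genes as the real one numbered 1 in each genotype and stimulation comparison and 10, 10 and 2 in the niacin comparisons, where the 10 follow from a real count of 0 and decide nothing.

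Interferon genes were lower with niacin in all 4 backgrounds. The exact permutation of niacin gave an adjusted p of 0.00195 for this list. That test was chosen after the fall had been seen in the same libraries, so its p does not exclude chance spread between libraries. Loss of another cell type that itself held these transcripts stays open. The summed CPM of myeloid, B cell and NK cell markers was higher with niacin in 3 backgrounds (changes of -145, 48.9, 161 and 92.4 CPM). The interferon sum changed by -1510, -852, -941 and -872 CPM. These sums follow the most abundant markers, and the lists hold H2-Ab1, which rose with stimulation in these cells. They cannot decide on the loss of a minor cell type, nor on a rare one that acts on the T cells. The mean log2 CPM of the myeloid, B cell and NK lists changed with niacin by -0.289, -0.019 and -0.356 in wild-type-labelled cells. In knockout-labelled cells it changed by 0.111, -0.047 and 0.311. The sort for CD3+CD4+ cells would also remove myeloid, B and NK cells. Niacin acting through the targeted receptor alone is argued against by a fall within both labels (exact p = 0.02 in knockout-labelled and 0.005 in wild-type-labelled libraries). That argument rests on the same permutation, chosen afterwards, and needs 1 label to lack the receptor in all its libraries. The candidate reference copy in knockout-labelled libraries numbered 1 leaves that open, and the test was not run without them. In knockout-labelled libraries 2 and 3 the mean log2 CPM was 5.59 and 4.95 stimulated without niacin, against 4.37 and 3.71 with it. Unstimulated, the values were 4.87 and 3.99, against 3.92 and 4.14. An effect of niacin on interferon signalling that needs no Hcar2 may remain, as a hypothesis found and tested on the same libraries, and effects of 5 mM niacin on the culture itself were not tested.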
